A study of Mus musculus with 9 samples.

How the data were processed

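RNA selection, read length, alignment settings and the counting tool are not given in the sources used here. Per the labels' protocols, RNA was extracted from mouse liver with Trizol and libraries were built from total RNA with an Illumina kit. The authors deposited a table of raw counts per gene for 9 libraries, and a table of FPKM (counts scaled by gene length and by a library total). Per the submitters' processing notes, Bowtie 0.12.2 and the builds mm8 and mm10 were named, with no role given for any of them. The gene identifiers and coordinates in the deposited tables are those of the C57BL/6NJ strain assembly, so no coordinates of another build were used. Each deposited FPKM value equalled the count divided by the gene length and by 1 effective total per library, and these totals equalled size factors of the kind DESeq2 computes times a common total (ratio 1 in all 9 libraries). The tables held 42188 genes, of which 17284 had no count in any library, 11779 had no gene symbol and 1092 were gene models named by the authors' pipeline.

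Libraries were grouped by their titles, with 3 per group. Columns headed by the letter M were matched to MSA_ConA, the group whose name begins with it. The labels' batch tag repeats the group and gives no batch. Labels say that 3 mice per group were used and that mice were randomized; p-values measure the spread between these 3 libraries.

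Totals ran from 13294600 to 17276391 counts, and 3 counts, taken as the floor for a gene at 0, equal 0.174 to 0.226 CPM of the total. CPM values in the text are scaled by TMM factors (trimmed mean of M values, 0.571 to 1.26). The test before the data were examined was set as edgeR 4.0.16 quasi-likelihood (R 4.3.3) on the deposited counts, with TMM, the default expression filter by group (14603 genes kept), all 9 libraries in 1 fit with 6 residual degrees of freedom and a Benjamini-Hochberg adjusted p under 0.05. Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), relative log expression or library totals in place of TMM, TMM without the 20 genes with the most counts, no filter, a CPM of at least 1 in at least 3 libraries, only the groups compared, the library number as a block, a stricter adjusted p of 0.01, an absolute log2 fold change of at least 1, limma on log2(FPKM + 1) of the deposited values, and leaving out each library in turn.

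Before the data were examined, 44 gene lists were fixed. Of their 879 entries 816 matched a gene name in the table and 2 a synonym, and 41 lists had at least 5 tested members. Lists were tested against all other genes with camera at a preset correlation of 0.01, adjusted over lists by Benjamini-Hochberg, and again with an estimated correlation and with fry. Named genes followed a rule fixed at the same time: the 5 largest changes each way among called genes, of which there were none, the 2 to 4 members with the smallest p in the 10 leading lists of a comparison, and Ifng, Tnf, Il1b, Il6, Il10, Acod1, Hmox1, Nqo1, Sod2, Cat and Alb. Sod2 has no gene of that symbol in the table and is not analysed here. Il1b measured 18.3 CPM in the library labelled ConA 1 and 1.25 to 2.52 CPM in the 8 others.

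Whether library numbers pair the samples was checked on deviations from the group means across genes. Same-numbered libraries correlated at 0.479 to 0.713 for number 1, 0.349 to 0.553 for number 2 and 0.303 to 0.472 for number 3. All lay over the bound of 0.1 set beforehand for taking the numbers to pair libraries. Numbers 2 and 3 correlated with each other as highly (0.313 to 0.681), so the check does not show pairs within these numbers. Number 1 correlated negatively with both (-0.676 to -0.373), a sign that centring on means of 3 libraries favours. The main fit used no block, and the library number entered as a block among the alternatives.

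After the division by number was seen, these steps were added: a fit on the libraries numbered 2 and 3, a block for number 1 against the others, a test of whether an effect differs between number 1 and numbers 2 and 3 in 1 model with a mean per group and per number class, and ratios between single libraries numbered 1. Libraries were divided by their number as labelled, which also divides the untreated ones, and not by their response. For single libraries, genes were named by list (up to 5 members of at least 10 CPM, by size) and by size (the 6 highest and 6 lowest ratios with at least 50 CPM in the higher library), a rule also chosen after the values were seen; 4-fold counts and medians of lists used log2(CPM + 1), and medians were ranked among 10000 random lists drawn from 20 bins of mean expression. The 14 skeletal muscle markers and the sex and strain genes were chosen at that stage too.

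The scripts were tested on simulated counts drawn from the real means, totals and dispersions, with 200 changed genes, 50 at each fold. For ConA against Control (14409 genes) the test on all 9 libraries recovered 0% of 2-fold, 10% of 4-fold, 38% of 8-fold and 68% of 16-fold changes, with 2 false calls. For MSA_ConA against ConA (14401 genes) the shares were 0, 2, 34 and 58% and for MSA_ConA against Control (14338 genes) 0, 4, 32 and 62%. In these runs on all 9 libraries, each fold was put on every library of a group. Counts were drawn without a division by number. The shares therefore do not apply to a response carried by a single library. On numbers 2 and 3 the shares for ConA against Control (14561 genes) were 36, 94, 98 and 98%, with 11 false calls, and there were 22 and 21 false calls in the other comparisons, a share of calls above the 5% aimed at. The test of a difference between numbers, for ConA against Control (14443 genes), recovered 14, 60, 92 and 92% with 14 false calls, also above that share. In the simulation of camera, a list raised 4-fold was found and 0 of the other lists passed. Genes were drawn there independently of each other and without a division by number. This run therefore does not measure false list calls among correlated genes.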

Results

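Liver RNA was sequenced from 9 mice in 3 groups of 3. Control mice were given phosphate-buffered saline into the tail vein. ConA mice were given 20 mg/kg of concanavalin A by the same route, a plant lectin that activates T cells and brings on immune-mediated hepatitis in mice. MSA_ConA mice were also given 250 mg/kg of MSA into the peritoneum, 6 h before the same dose of concanavalin A. The study's title names mesaconate, a metabolite related to itaconate, and MSA was read as that compound. Livers were collected 12 h after concanavalin A. Per the labels, every mouse was an 8-week-old C57BL/6J male of 20 to 25 g, and every library carries a number from 1 to 3 within its group. The deposited table held 13294600 to 17276391 counts per library over 42188 genes, of which 14603 were tested. A single count was worth 0.0579 to 0.0752 CPM, the unit that scales a library's total to 1e6 counts.

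Transcripts that tell sex and strain apart divided the libraries by their number and went against the labels of 6 of them. Xist, the RNA that coats the inactive X chromosome of female cells, measured at most 0.484 CPM in the 3 libraries numbered 1 and 667 to 1131 CPM in the 6 numbered 2 or 3. Mup21, a major urinary protein gene made mainly by male liver, measured 251 to 668 CPM in number 1 and at most 1.44 CPM in the others, with the caution that genes of this family share reads with near-identical copies. Nnt, a mitochondrial transhydrogenase that is partly deleted in C57BL/6J, measured 29.8 to 34.5 CPM in number 1 and 168 to 266 CPM in the others. H2-K1, a class I histocompatibility gene that varies in sequence between strains, measured 2021 to 8625 CPM in number 1 and 100.2 to 165 CPM in the others. Genes of the circadian clock divided the same way: Arntl measured 22.0 to 29.5 CPM in number 1 and 1.35 to 3.60 CPM in the others, while Dbp measured 6.00 to 10.3 CPM against 99.7 to 251 CPM. These genes were chosen after their values were seen. Y-linked genes were not analysed here. Since the values and the labels conflict, each library is named by its label, as in "the library labelled ConA 1".

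**Figure D1:**
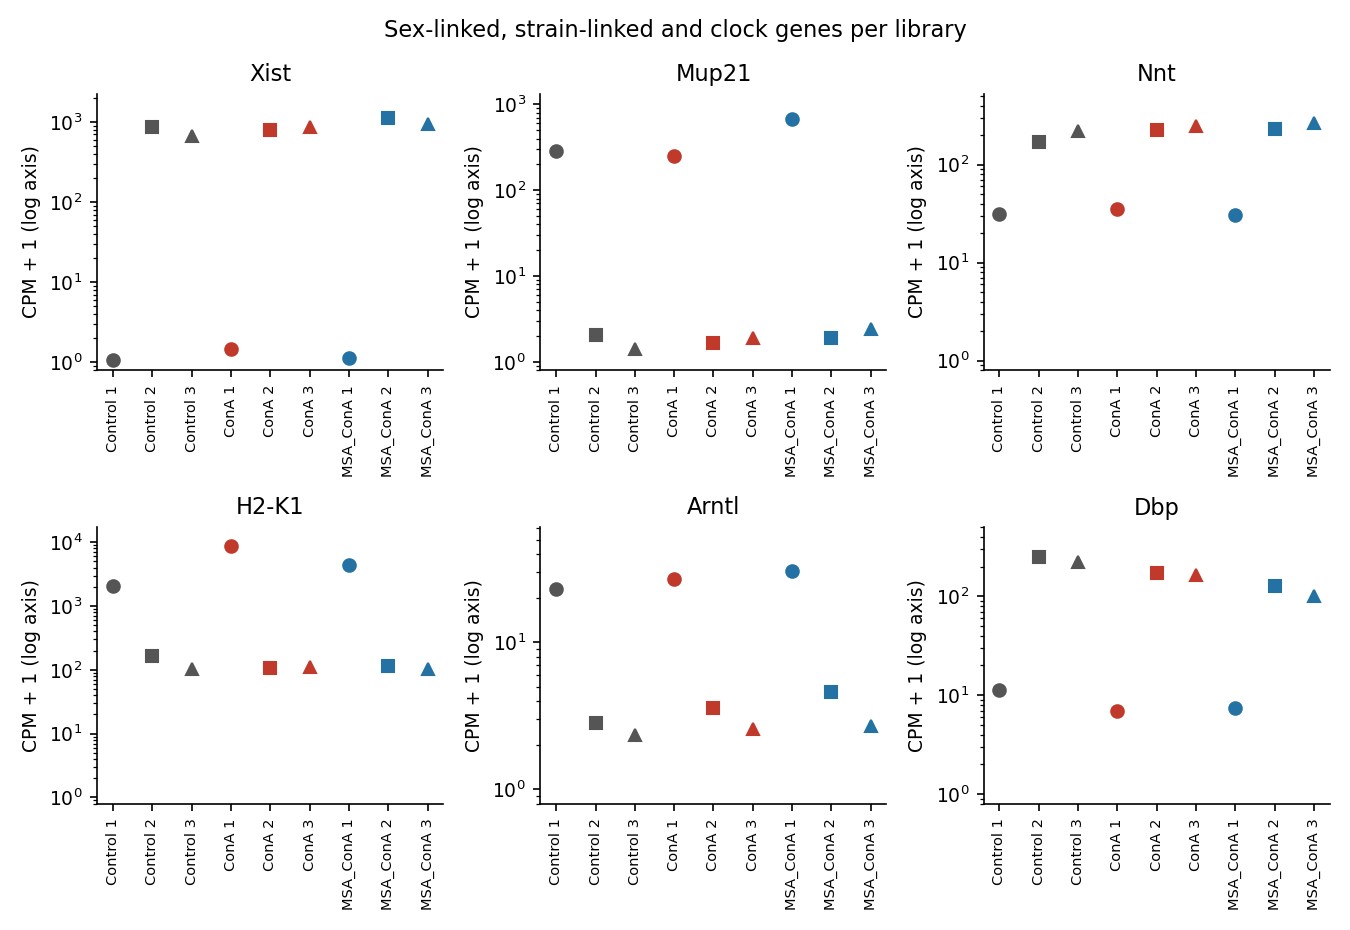
CPM + 1 on a log axis for Xist, Mup21, Nnt, H2-K1, Arntl and Dbp in each of the 9 liver libraries, 1 point per library, with grey for Control, red for ConA and blue for MSA_ConA and with circles, squares and triangles for numbers 1, 2 and 3. The circles lie apart from the other points in every panel, as for Xist with at most 0.484 CPM in number 1 and at least 667 CPM elsewhere.

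The division by number ran through the whole transcriptome. Growth hormone-responsive male liver genes, a list fixed beforehand, were higher in number 1 than in numbers 2 and 3, with a median log2 ratio of 2.46 over 11 measured members. Of these, 8 rose and 2 fell in edgeR's quasi-likelihood test with the group in the model, and the list had an adjusted p of 1.72e-08 by camera, or an adjusted p of 0.210 with an estimated correlation. The same model called 5592 of the 14603 genes at a Benjamini-Hochberg adjusted p under 0.05, 2785 higher and 2807 lower in number 1. The responses of ConA 1 and MSA_ConA 1 enter these calls too: acute-phase proteins led the lists (median 2.83, 21 of 27 passed upward, adjusted p = 6.64e-09 by camera, or adjusted p = 0.700 with an estimated correlation). The first principal component held 60.1% of the variance and placed the libraries labelled ConA 1, MSA_ConA 1 and Control 1 at -153, -153 and -40.5, and the 6 others between 40.4 and 71.0. Across genes, which are not independent replicates, log2 CPM correlated at 0.964 to 0.983 between numbers 2 and 3 of a group and at 0.761 to 0.902 between number 1 and either. No pair of libraries of the same group agreed within counting noise.

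**Figure D2:**
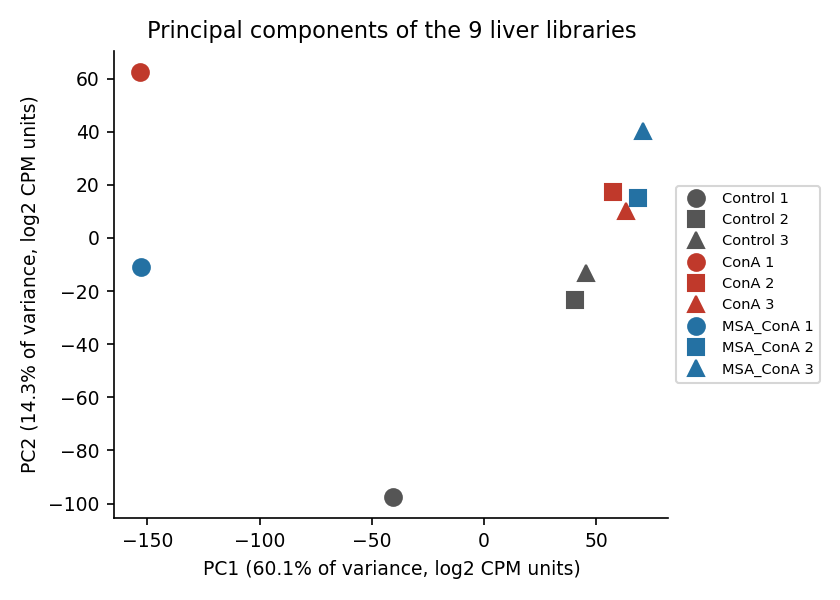
First and second principal components of log2 CPM for the 9 liver libraries, 1 point per library, with colour for the group and shape for the number. PC1 holds 60.1% of the variance and places the circles of number 1 at negative values, from -153 to -40.5, and the 6 other libraries between 40.4 and 71.0.

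The comparison of ConA with Control addresses what concanavalin A did to the liver. Inflammatory, acute-phase and apoptosis genes were higher in ConA as lists by camera with its preset correlation, with adjusted p = 0.673 with an estimated correlation. They were high in the library labelled ConA 1 and near control level in those labelled ConA 2 and ConA 3. In ConA 1, Cxcl10, a chemokine that attracts T cells, measured 3505 CPM, against 3.65 and 2.27 CPM in ConA 2 and ConA 3 and 2.13 to 13.9 CPM in the controls. Tnfaip3, a feedback inhibitor of NF-kappa-B, measured 1072 CPM in ConA 1, 4.43 and 4.88 CPM in the other ConA libraries and at most 3.29 CPM in Control. Hmox1, the haem-degrading oxygenase induced by oxidative stress, measured 3514 CPM in ConA 1, 14.5 and 13.1 CPM in the other ConA libraries and 17.5 to 19.0 CPM in Control.

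Over all 9 libraries, 13 of the 41 fixed lists tested passed camera's threshold, 10 upward and 3 downward. NF-kappa-B targets and adhesion molecules rose as a list, with all 20 members higher and a median log2 fold change of 2.80 (adjusted p = 1.92e-10). Of the interferon gamma-induced genes 22 of 23 were higher (median 2.37, adjusted p = 3.48e-06), and of the acute-phase proteins 26 of 27 (1.65, 0.000138). All 13 chemokines were higher (2.18, 0.000902), as were 20 of 22 apoptosis and p53 targets (1.10, 0.000499) and 20 of 23 type I interferon-induced genes (1.70, 0.00136). Smaller shifts passed for extracellular matrix genes (0.66), monocyte and recruited macrophage markers (1.05), and T and NK cell markers (0.74; adjusted p = 0.0678 with the library number as a replicate block). Kupffer cell markers fell as a list (12 of 14 lower, median -0.46, adjusted p = 0.00785), with Clec4f, a lectin of resident liver macrophages, at 77.5 ± 22.9 CPM in ConA and 142 ± 42.4 CPM in Control (SD, n = 3). B and plasma cell markers (-0.56) and cholesterol synthesis genes (-0.27) also fell as lists. Adipocyte markers rose (5 of 6, median 2.60, adjusted p = 0.0165), with median log2 ratios of 1.92, 0.77 and 0.13 in numbers 1, 2 and 3. Separately, 14 skeletal muscle markers summed to 407 and 77.6 CPM in ConA 2 and ConA 3, 7.26 CPM in ConA 1 and at most 21.4 CPM in Control. With an estimated correlation no list passed, each of the 13 having an adjusted p of 0.673.

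No single gene passed between ConA and Control in edgeR's quasi-likelihood test (0 of 14603, smallest adjusted p 0.9997). In all 3 comparisons, the spread within groups that this test uses includes the division by number. A count of 0 therefore does not show a lack of effect. At an unadjusted p under 0.05 there were 563 genes, where chance gives 730. None of the members adjusted over the list alone passed in any called list. Tnfaip3 had a log2 fold change of 7.15 (SE 2.09), Icam1, the adhesion molecule that binds leukocytes, 4.89 (SE 1.62), and Gbp5, an interferon-induced GTPase, 5.52 (SE 1.72), each with an adjusted p of 0.9997 by edgeR. limma-voom also called 0 genes (240 unadjusted), and DESeq2 called 3 (801 unadjusted), namely Myl1, Myh2 and Atp2a1, which encode skeletal muscle proteins. Without the library labelled ConA 1, 2 of the 13 list calls kept their direction, and type I interferon-induced genes were called downward (adjusted p = 0.0155 by camera, or adjusted p = 0.806 with an estimated correlation).

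In the libraries numbered 1, with 1 library per group and no replicate check, 858 genes of at least 10 CPM in the higher library were at least 4-fold higher and 351 at least 4-fold lower in ConA than in Control, as ratios of CPM + 1. The same counts were 51 and 4 in number 2 and 8 and 2 in number 3. Intervals for single-library ratios are exact 95% limits that cover counting error only. The NF-kappa-B list had a median log2 ratio of 4.10 in number 1 with 20 of 20 members at least 4-fold higher, and 0.04 and 0.00 in numbers 2 and 3. Tnfaip3 was 757-fold higher (485 to 1259) and Icam1 87.3-fold (76.8 to 99.6). Interferon gamma-induced genes had a median of 3.43 in number 1 and -0.05 in both other numbers, with Gbp2 251-fold higher (187 to 346) and the T cell-attracting chemokine Cxcl9 222-fold (197 to 252). Acute-phase proteins had a median of 2.91, with the metallothionein Mt2 333-fold higher (302 to 367), Saa3 242-fold (218 to 268) and the siderophore-binding Lcn2 181-fold (169 to 194). Each of these 3 medians lay above those of all 10000 random lists matched on expression. Random genes were drawn independently, while members of a list can move together, so this rank does not measure variation between animals.

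Other members of the same library pair moved with them. The stress hormone gene Gdf15 was 238-fold higher (199 to 287) and the cell cycle inhibitor Cdkn1a 82.6-fold (69.0 to 99.7). S100a9, a calcium-binding protein of neutrophils, measured 261 CPM in ConA 1 and 1.64 CPM in Control 1. Acod1, which makes itaconate, measured 49.2 CPM against 0.0745 CPM, a ratio of 661 (118 to 26166) resting on 1 count in Control 1. The cytokine transcripts themselves were scarce: Ifng measured 2.71 and 0.521 CPM, and Tnf 14.6 and 0.670 CPM. Il6 measured 4.74 CPM against no count, which makes it at least 21.2-fold higher against a floor of 3 counts. The lists of bile acid synthesis and transport (4 of 19 higher), cholesterol synthesis and lipogenesis had medians of -0.70, -0.69 and -0.84, while gluconeogenesis and fatty acid oxidation genes went both ways (8 of 18 and 12 of 25 higher). Single genes that were lower include G6pc, the last enzyme of gluconeogenesis (75.4-fold, 59.8 to 96.5). Nr0b2, a repressor gene on the bile acid list, was 52.5-fold lower (32.6 to 90.4). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 8.37-fold lower (6.46 to 11.01). Alb, the gene of albumin, measured 64100 CPM in ConA 1 and 76678 CPM in Control 1.

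**Figure D3:**
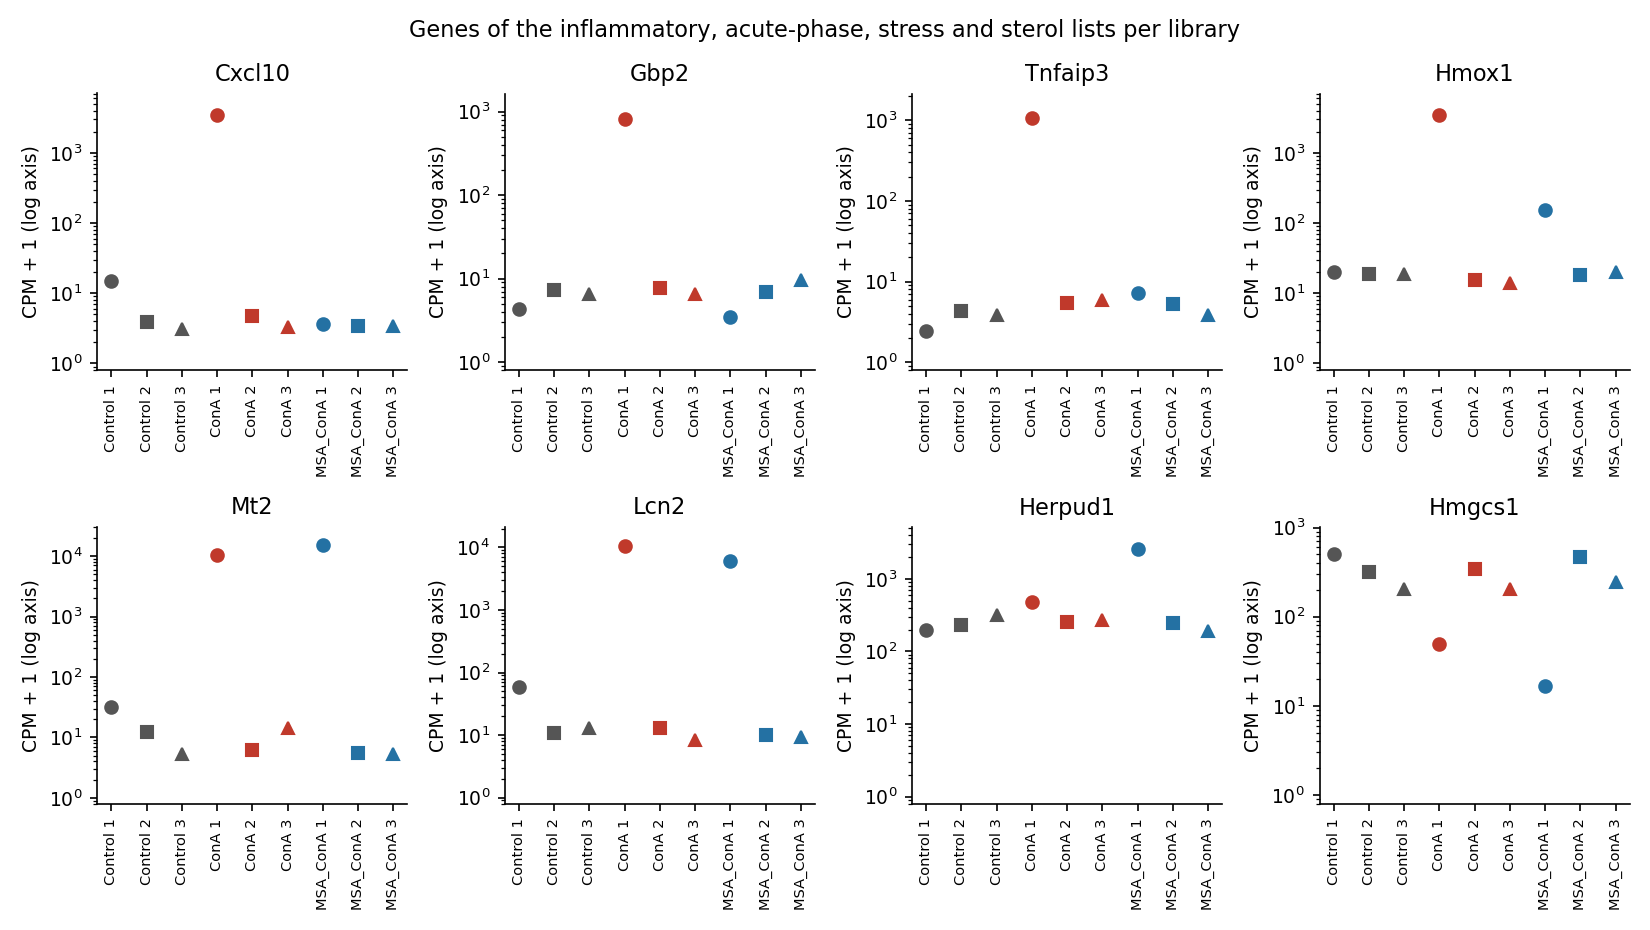
CPM + 1 on a log axis for 8 genes in each of the 9 liver libraries, 1 point per library, with grey for Control, red for ConA and blue for MSA_ConA and with circles, squares and triangles for numbers 1, 2 and 3. Cxcl10 reaches 3505 CPM in the library labelled ConA 1 and 2.63 CPM in MSA_ConA 1, while Mt2 measures 10435 and 15180 CPM in these libraries and at most 31.4 CPM in the 7 others.

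The effect of ConA differed between number 1 and numbers 2 and 3 for 4537 of 14603 genes in a test of the difference itself (edgeR, Benjamini-Hochberg), 2287 higher and 2250 lower in number 1. Tnfaip3, Cxcl9, Icam1 and Hmox1 each had an adjusted p of 0.000138 in this edgeR test, and Cat, the gene of catalase, had one of 0.0558. The test has 3 residual degrees of freedom and assumes that the lone library numbered 1 in each group varies like those numbered 2 and 3. In the libraries numbered 2 and 3 alone, edgeR called 0 of 14851 genes (1725 at an unadjusted p under 0.05, where chance gives 743; smallest adjusted p 0.414). There, nuclear genes of oxidative phosphorylation (22 of 24 lower, median -0.35, adjusted p = 3.28e-08 by camera) and hepatocyte identity genes (16 of 20 lower, median -0.30, adjusted p = 4.89e-05) fell as lists. Kupffer cell markers (-0.22) and antioxidant enzymes (-0.23) also fell and adipocyte markers rose (10 of 10). Of the adipocyte markers, Fabp4 measured 39.3 CPM in ConA 2 and 5.56 CPM in ConA 3, against 7.775 and 5.36 CPM in Control 2 and Control 3. Muscle markers summed to 407 and 77.6 CPM in the ConA libraries of this fit and 4.17 and 1.56 CPM in its controls. None of these 5 lists passed with an estimated correlation, with adjusted p = 0.951.

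The comparison of MSA_ConA with ConA addresses what MSA given beforehand changed. Interferon-induced genes, NF-kappa-B targets and chemokines were lower in MSA_ConA as lists by camera with its preset correlation, with adjusted p = 0.654 with an estimated correlation. The libraries numbered 1 carried the difference. Cxcl10 measured 2.63 CPM in the library labelled MSA_ConA 1, 1331-fold (862 to 2179) below ConA 1, and 2.38 and 2.42 CPM in those labelled MSA_ConA 2 and MSA_ConA 3. Hmox1 measured 152 CPM in MSA_ConA 1, 23.2-fold (21.8 to 24.6) below ConA 1. Acute-phase transcripts were divided: Crp, the gene of C-reactive protein, and Cd14, a receptor for bacterial lipopolysaccharide, measured 114 and 152 CPM in MSA_ConA 1 and 2101 and 1275 CPM in ConA 1. Mt1, Mt2, Lcn2 and Hp, the gene of haptoglobin, measured 18694, 15180, 6026 and 59592 CPM in MSA_ConA 1 and 11689, 10435, 10608 and 41859 CPM in ConA 1.

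Over all 9 libraries 12 of 41 lists passed, 11 downward and 1 upward. NF-kappa-B targets and adhesion molecules fell as a list, with 20 of 20 members lower (median log2 fold change -2.90, adjusted p = 4.06e-13 by camera). Of the interferon gamma-induced genes 23 of 23 were lower (-2.35, 6.31e-13), and of the type I interferon-induced genes 22 of 23 (-1.85, 1.61e-09). Chemokines (11 of 13 lower, -1.58, 5.65e-05) and NRF2 targets (22 of 24 lower, -0.33, 0.000237) fell too; NRF2 is the transcription factor that drives antioxidant and detoxifying enzymes. Further lists passed downward: cholangiocyte markers (-0.90), T and NK cell markers (-0.65), dendritic cell markers (-1.26), antigen presentation by MHC class II (-0.74), cytokines and their antagonists (-0.96; adjusted p = 0.0631 with the replicate block) and extracellular matrix genes (-0.43). Nuclear genes of oxidative phosphorylation rose (23 of 24, median 0.25, adjusted p = 0.0466). With an estimated correlation none of the 12 passed, with adjusted p from 0.654 to 0.826.

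No gene passed between MSA_ConA and ConA in edgeR's test (0 of 14603, smallest adjusted p 0.9999; 248 at an unadjusted p under 0.05, where chance gives 730). limma-voom called 0 (43 unadjusted) and DESeq2 called 1 (406 unadjusted), an unnamed gene. That gene measured 3.84 CPM of the library total in MSA_ConA 1 and had no count in any other library. Cxcl10 had a log2 fold change of -8.88 (SE 2.75), Irf1, a transcription factor induced by interferon gamma, -4.55 (SE 1.44), and Srxn1, a reductase driven by NRF2, -2.68 (SE 1.04), each with an adjusted p of 0.9999 by edgeR. Without ConA 1, 1 of the 12 list calls kept its direction, and 0 with an estimated correlation. In numbers 2 and 3 alone, no gene passed (767 unadjusted, chance 743; smallest adjusted p 0.611 by edgeR), and 2 lists were called in the opposite direction, interferon gamma-induced genes (18 of 23 higher, median 0.24, adjusted p = 0.0141 by camera) and type I interferon-induced genes (21 of 23 higher, 0.40, 6.69e-05). Sinusoidal endothelial markers also rose there (0.14), and unfolded protein response (-0.19), periportal (-0.19), pericentral (-0.17), gluconeogenesis (-0.20) and hepatocyte identity genes (-0.13) fell as lists. Lists differed in which number carried them: medians in numbers 2 and 3 were 0.08 and -0.37 for the periportal list, 0.35 and 0.24 for type I interferon and -0.19 and -0.16 for the unfolded protein response. The library labelled MSA_ConA 3 held 5153 CPM of muscle markers. All 8 lost the call with an estimated correlation, with adjusted p = 0.987.

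Among the libraries numbered 1, 544 genes were at least 4-fold lower and 240 at least 4-fold higher in MSA_ConA than in ConA. Median log2 ratios of the interferon gamma, NF-kappa-B and type I interferon lists were -3.96, -3.65 and -3.34. They lay below those of all 10000 random lists, a rank that again does not measure variation between animals. Gbp2 was 329-fold lower (211 to 547), Tnfaip3 170-fold (128 to 230), Irf1 123-fold (101 to 149.5) and the interferon-induced Ifit1 146-fold (85.2 to 275). NRF2 targets had a median of -0.92, with Gclc, which makes the first step to glutathione, 20.7-fold lower (18.5 to 23.2) and Srxn1 17.05-fold (15.1 to 19.3). Acod1 was 46.7-fold lower (23.5 to 109), at 1.05 CPM. Acute-phase proteins had a median of -0.02, with 12 of 27 members higher and 4 at least 4-fold lower, among them Saa3 (109.7-fold, 100.1 to 120.5), Crp (18.4-fold, 17.2 to 19.8) and Cd14 (8.39-fold, 7.90 to 8.92). Higher in MSA_ConA 1 were Thrsp, which promotes lipogenesis (11.6-fold, 11.3 to 11.98), and Herpud1, a gene of the unfolded protein response (5.42-fold, 5.25 to 5.59). The effect differed between number 1 and numbers 2 and 3 for 2724 genes in edgeR's test of the difference (1255 higher and 1469 lower in number 1; 1368 in all without ConA 3 and 1631 without ConA 2), among them Cxcl10, Gbp2, Irf1 and Hmox1 with an adjusted p of 0.000262 each.

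The comparison of MSA_ConA with Control addresses what set MSA-pretreated livers apart from untreated ones. Acute-phase proteins were higher and cholesterol synthesis genes lower as lists by camera with its preset correlation, with adjusted p = 0.988 with an estimated correlation. The acute-phase call was also lost with the library number as a block (adjusted p = 0.0896) and ran the other way in numbers 2 and 3. In the library labelled MSA_ConA 1, Mt2 measured 15180 CPM against 31.4 CPM in Control 1, and Hmgcs1, which makes the substrate of the mevalonate pathway, measured 15.8 CPM against 506 CPM. In numbers 2 and 3, Mt2 measured 4.54 and 4.38 CPM in MSA_ConA against 11.2 and 4.21 CPM in Control, and Hmgcs1 461 and 247 CPM against 319 and 203 CPM.

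Over all 9 libraries 4 of 41 lists passed. Cholesterol synthesis and uptake genes fell (18 of 21 lower, median -0.36, adjusted p = 0.00261 by camera), with Mvd, an enzyme of the mevalonate pathway, at 16.8 ± 7.58 CPM against 49.8 ± 21.5 CPM (SD, n = 3). Kupffer cell markers fell (10 of 14 lower, -0.29, adjusted p = 0.0347), acute-phase proteins rose (24 of 27 higher, 1.86, 0.0347) and adipocyte markers rose (5 of 6 higher, 2.89, 0.0347). Muscle markers summed to 395 and 5153 CPM in MSA_ConA 2 and MSA_ConA 3, 11.7 CPM in MSA_ConA 1 and at most 21.4 CPM in Control. With an estimated correlation none of the 4 passed, with adjusted p = 0.988. With the library number as a replicate block 2 of the 4 passed, the cholesterol (adjusted p = 0.00164) and Kupffer cell lists (0.00589).

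No gene passed between MSA_ConA and Control in edgeR's test (0 of 14603, smallest adjusted p 0.937; 730 at an unadjusted p under 0.05, the number chance gives) or in limma-voom (0, 492 unadjusted). DESeq2 called 64 (1104 unadjusted), 62 higher and 2 lower; of these 8 are muscle markers and 57 had their highest value in MSA_ConA 3. Mvd had a log2 fold change of -1.57 (SE 0.49) and Herpud1 one of 2.02 (SE 0.93), each with an adjusted p of 0.937 by edgeR. Without MSA_ConA 1, 1 of the 4 list calls kept its direction. In numbers 2 and 3 alone no gene passed (3578 unadjusted, chance 743; smallest adjusted p 0.0823 by edgeR), acute-phase proteins were called downward (21 of 27 lower, median -0.36, adjusted p = 0.0155 by camera), and hepatocyte identity genes fell (18 of 20 lower, -0.41, 3.58e-06). Oxidative phosphorylation (-0.25), antioxidant (-0.33), periportal (-0.31) and complement and coagulation genes (-0.15) fell there. Adipocyte markers rose (10 of 10), with the members Fabp4 and Cfd at 71.7 and 18.6 CPM in MSA_ConA 3. These 2 measured 6.64 and 0.553 CPM in MSA_ConA 2 and at most 7.775 and 1.36 CPM in Control 2 and Control 3. None of the 7 lists passed camera with an estimated correlation (adjusted p = 0.979).

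Between the libraries numbered 1, 661 genes were at least 4-fold higher and 440 at least 4-fold lower in MSA_ConA than in Control. Acute-phase proteins had a median log2 ratio of 2.69, with Mt2 484-fold higher (439.96 to 534) and Lcn2 103-fold (95.8 to 110.5). Unfolded protein and integrated stress response genes had a median of 1.24, with Herpud1 13.1-fold higher (12.6 to 13.7) and the endoplasmic reticulum chaperone Hspa5 7.14-fold (6.97 to 7.31). Tat, a glucocorticoid-responsive enzyme of tyrosine breakdown, was 10.6-fold higher (10.4 to 10.8) and Cdkn1a 137-fold (115 to 166). Cholesterol genes had a median of -1.71, with Hmgcs1 32.0-fold lower (26.7 to 38.7). Type I interferon-induced genes lay below the control library at -1.18, with Ifit1 11.3-fold lower (6.47 to 21.5). Ifit1 measured 1.71 CPM in MSA_ConA 1 and 19.3 CPM in Control 1, against 5.375 and 4.68 CPM in Control 2 and Control 3. How much of the gap lies with Control 1 cannot be told with 1 library per group. The interferon gamma and NF-kappa-B lists had medians of -0.29 and 0.20. Nqo1, an NRF2-driven quinone reductase, was 5.56-fold lower (3.42 to 9.60), and Cat 2.86-fold (2.80 to 2.93). The effect differed between number 1 and numbers 2 and 3 for 4767 genes in edgeR's test of the difference (2342 higher and 2425 lower in number 1), with adjusted p of 0.00120 for Mt2, 0.000786 for Herpud1 and 0.00234 for Hmgcs1.

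**Figure D4:**
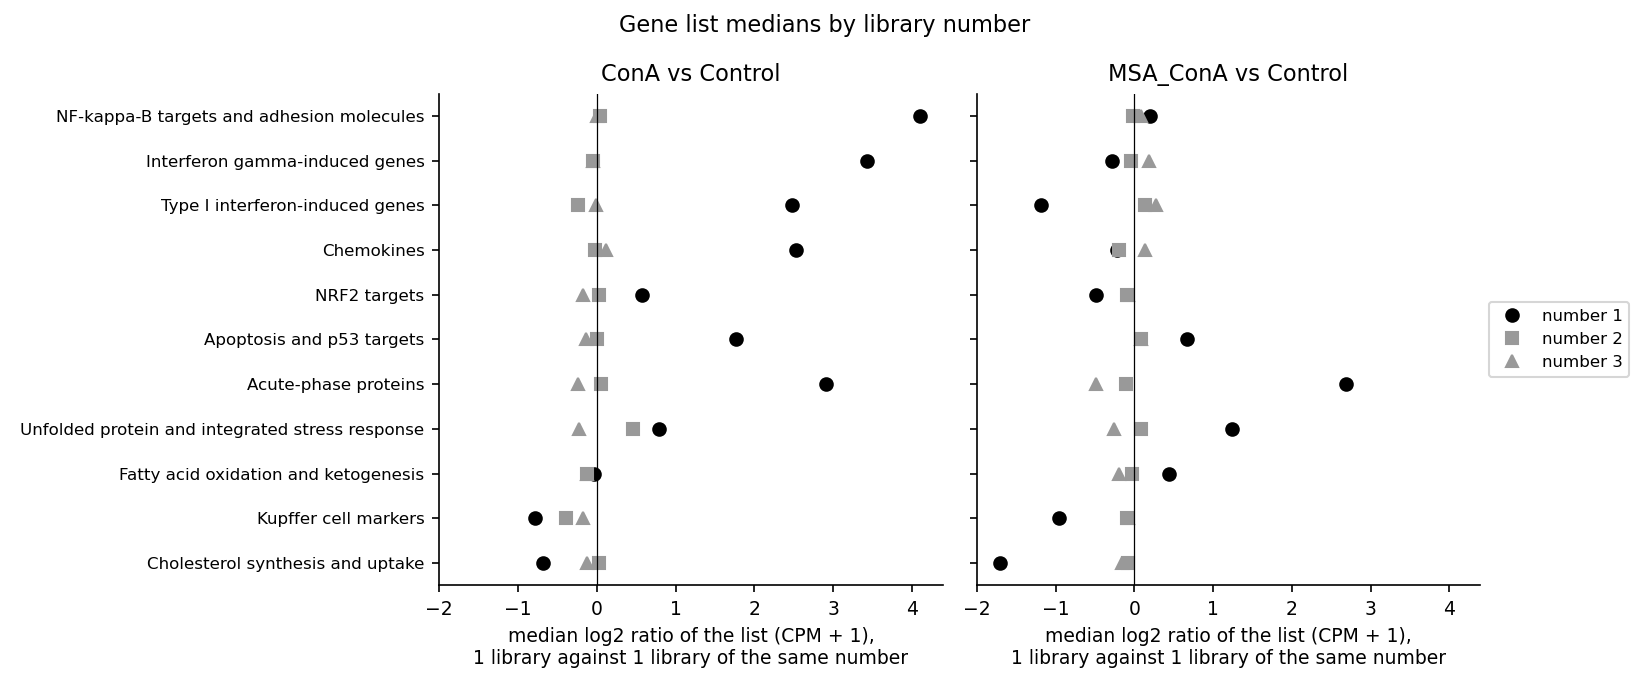
Median log2 ratio of CPM + 1 for 11 fixed gene lists, for ConA over Control and for MSA_ConA over Control, 1 library against 1 library of the same number, with black circles for number 1 and grey squares and triangles for numbers 2 and 3. In number 1 the NF-kappa-B list has a median of 4.10 for ConA and 0.20 for MSA_ConA, and the acute-phase list has 2.91 and 2.69.

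How far MSA brought the response to concanavalin A back was to be read from genes called in both comparisons with opposite signs. No gene was called in either by edgeR, so the count was 0. The number expected from independent lists was then 0 by construction. The mean of 20 simulations of unchanged groups that share the ConA libraries was also 0. Neither value tells whether MSA brought the response back. A slope of MSA_ConA on ConA effects could not be fitted for want of called genes. Within the libraries numbered 1, of the 858 genes at least 4-fold higher in ConA 1 than in Control 1, 334 were also at least 4-fold higher in MSA_ConA 1, 196 were 2- to 4-fold higher, 276 lay within 2-fold and 52 were at least 2-fold lower. Of the 351 genes at least 4-fold lower in ConA 1, 190 were at least 4-fold lower in MSA_ConA 1, 103 were 2- to 4-fold lower and 58 lay within 2-fold. Both ratios share the library labelled Control 1, and its own counting and animal variation enters both. In numbers 2 and 3, where few genes differed, 21 of 51 and 4 of 8 genes higher in ConA were also at least 4-fold higher in MSA_ConA, so these shares do not measure a return to control level. Cxcl9 and Gbp2 belong to the genes within 2-fold of Control 1, at 22.8 and 2.50 CPM in MSA_ConA 1 against 19.7 and 3.28 CPM.

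**Figure D5:**
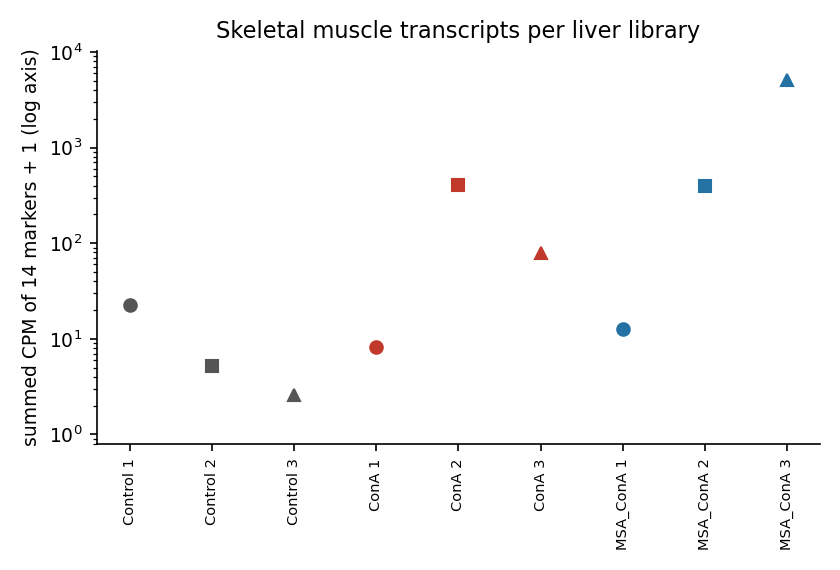
Summed CPM + 1 of 14 skeletal muscle markers on a log axis in each of the 9 liver libraries, 1 point per library, with colour for the group and shape for the number. The sums are 407 and 77.6 CPM in the libraries labelled ConA 2 and ConA 3 and 395 and 5153 CPM in MSA_ConA 2 and MSA_ConA 3, and at most 21.4 CPM in the 5 others.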

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

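The tests of explanations in this part were chosen or worded only after the results they measure had been seen. The DESeq2 calls and the real counts of genes and lists repeated here come from planned fits. Effects differed between number 1 and numbers 2 and 3 for 4537 genes in ConA against Control, 2724 in MSA_ConA against ConA (1368 without ConA 3) and 4767 in MSA_ConA against Control, by edgeR's test of the difference itself. Number 1 has 1 library per group there, all 3 residual degrees of freedom come from numbers 2 and 3, and in simulated counts false calls exceeded 5% of the calls, so these counts hold only if the lone libraries vary like the others.

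The first pattern is that the libraries numbered 1 stand apart in every group, the untreated one included. That the animals numbered 2 and 3 were female is one candidate explanation, and the lowest Xist level of their 6 libraries was 667 CPM, where male liver would give next to none. Another mouse strain is a second one: Nnt in those 6 libraries was at least 4.86 times its highest level in number 1, and H2-K1 was at most 165 CPM against at least 2021 CPM. Livers taken at another time of day may add to it, since Arntl in Control 1 was 12.1 times the higher of Control 2 and Control 3, with Dbp lower. Sex, strain and hour are bound together here, and the responses of ConA 1 and MSA_ConA 1 enter as well (acute-phase median 2.83), so the shares of each in the 5592 genes stay open.

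The second pattern is the inflammatory response, high in ConA 1 and near control level in ConA 2 and ConA 3. Labels exchanged between treated and control libraries numbered 2 and 3 are argued against as the source of this pattern. No library of the 6 carried a response: the highest median of the inflammatory lists over the other 5 libraries was 0.0595 on the log2 scale. If no animal numbered 2 or 3 responded, an exchange would leave no mark here, so whether these labels are right stays open. Scaling is argued against too, because with library totals only the interferon gamma list in ConA 1 over Control 1 kept a median log2 ratio of 2.94. Animals numbered 2 and 3 that were not exposed to concanavalin A, or were exposed and did not respond at 12 h, cannot be told apart: the acute-phase median there was -0.17, the labels give these animals the same dose, and no value tells exposure from response. Sex, strain or hour of day may also change the response itself, which the design leaves untested.

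The third pattern is muscle transcripts in the treated libraries numbered 2 and 3. Pieces of skeletal muscle, such as diaphragm, taken with the liver could account for them, since 13 of the 14 markers passed 1 CPM in MSA_ConA 3 with Acta1, a main muscle actin, at 1468 CPM; in the untreated libraries 0 to 2 markers did. An effect of the treatment cannot be told apart from this: the treated libraries numbered 1 summed to at most 11.7 CPM and Control 1 to 21.4 CPM, but 19.4 CPM of the latter come from Tpm2 alone, so their order decides nothing. Of the 64 genes DESeq2 called in MSA_ConA against Control, 8 are on the muscle list and 57 peak in MSA_ConA 3.

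Dividing each set of 6 libraries 3 against 3 gives 10 splits, too few for a share under 0.05. For genes past the threshold the real value was 0 and the highest other 0 in every comparison, so all 10 splits gave as many. For lists, ConA against Control gave 13 and the highest other split 20, with 9 of the 10 splits at least as high; MSA_ConA against ConA gave 12 and 20, and MSA_ConA against Control 4 and 17, each with 10 of the 10 at least as high. The 3 other splits that part all same-numbered pairs gave 13 to 16, 13 to 18 and 7 to 17 lists. Splits that put both libraries numbered 1 on the same side gave 575 to 1580, 2304 to 3022 and 500.0 to 1947 genes at an unadjusted p under 0.05, against real values of 563, 248 and 730. All 4 such splits exceeded the real one in the first 2 comparisons and 2 of the 4 did so in MSA_ConA against Control.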

How the results depend on the processing

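Fits on numbers 2 and 3 only, the block of number 1 against 2 and 3, the test of the difference between numbers, the fit on numbers 2 and 3 without MSA_ConA 3, and the estimated correlation without ConA 1 were chosen only after the data were seen; all other alternatives were planned. The count of genes past the threshold stayed at 0 in all 3 comparisons under every alternative except DESeq2, which gave 3, 1 and 64; the cause was not tested, and 57 of the 64 have their highest value in MSA_ConA 3. The count of genes called with opposite signs stayed at 0, and no fit called the 5 genes a slope needs. Log2 fold changes of 93 named genes gave 1946 values under alternatives with 0 calls gained, lost or reversed, and 80 changed sign without a call, 35 of them in numbers 2 and 3 only and 27 without ConA replicate 1.

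List calls depend on more. With an estimated correlation and with fry 0 lists passed in each comparison and in total, from 29 in all, and so it was with an estimated correlation without ConA 1. With the replicate block MSA_ConA against Control fell from 4 to 2 lists, and the block changed no other count by over 1.5 times (14, 13 and 29 in total), though it kept 12 of 13 and 11 of 12 calls and added 2 in each of these comparisons. Number 1 against 2 and 3 as a block gave 2 there. Numbers 2 and 3 only gave 5 lists for ConA against Control and 7 for MSA_ConA against Control; fewer and other libraries enter by construction. Leaving out each library gave 18 to 42 lists in total, 6 (without ConA 1) to 21 (without Control 1) for ConA against Control, 8 to 18 for MSA_ConA against ConA and 2 to 8 for MSA_ConA against Control. Genes whose effect differed between numbers ranged, without each library numbered 2 or 3, over 3071 to 4659, 1368 to 2403 (1368 without ConA 3) and 3646 to 4197.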

Other observations

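All tests and values in this part were chosen only after the data were seen, and single-library values have no replicate check. Of the 18 clock genes, 5 were highest in both treated libraries numbered 1 (Per1, Nfil3, Bhlhe40, Arntl and Cry2), while others such as Per2 were not (19.5 and 36.7 CPM against 81.5 to 128 CPM in numbers 2 and 3). Per1 measured 436 and 356 CPM in the libraries labelled ConA 1 and MSA_ConA 1, 6.26 CPM in Control 1 and 14.9 to 36.1 CPM in numbers 2 and 3. Nfil3, a repressor of clock output genes, measured 485 and 568 CPM in these libraries, 29.6 CPM in Control 1 and at most 15.7 CPM elsewhere. Bhlhe40 measured 1677 and 633 CPM against 44.2 CPM in Control 1 and 132 to 179.5 CPM in numbers 2 and 3. Igfbp1, a fasting- and stress-induced binding protein, measured 5331 and 3226 CPM against 46.8 CPM in Control 1 and at most 16.3 CPM in numbers 2 and 3.

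Among the libraries numbered 1, 12 of 14 Kupffer cell markers were lower in ConA than in Control (median log2 ratio -0.78), and 2 were higher, Marco among them. Clec4f and Vsig4 measured 51.4 and 6.58 CPM in ConA 1 and 57.8 and 8.29 CPM in MSA_ConA 1, against 185 and 25.2 CPM in Control 1. Marco, a scavenger receptor, measured 59.1 CPM in ConA 1 and 18.2 CPM in both MSA_ConA 1 and Control 1.

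Among the genes that were highest in MSA_ConA 1, Fbf1 measured 2065 CPM against 34.2 CPM in ConA 1 and 15.4 CPM in Control 1. Zpr1, a zinc finger protein gene on chromosome 9, measured 4814 CPM in MSA_ConA 1 and 102 CPM in ConA 1.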
